A study of Mus musculus with 8 samples.

How the data were processed

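Polyadenylated RNA of 8 libraries was sequenced on an Illumina platform after TruSeq preparation, per the labels' protocols: 4 libraries of mouse embryonic stem cells (mESC) from 2 lines and 4 of epiblast stem cells (mEpiSC) from 3 lines. The deposited values are FPKM per gene and library, with the bounds of a 95% interval and a status. Per the submitters' processing notes they were made with TopHat2 2.0.6 and Cufflinks 2.0.2 on the mouse genome mm9; the annotation, the options and the use of strand are not given in the sources used here. Each library has its own table, so replicates were not pooled, and 0 columns of per-sample values were left unused. Without a statement on strand, reads of a gene and of an overlapping or antisense gene cannot be told apart.

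Each table listed 23699 entries. Symbols at several loci (248 symbols, 712 entries, 20 of them at 1 FPKM or more in at least 4 libraries) were left out, because the tables do not say how their reads were divided, which left 22987 genes at 1 locus. In each library 285 entries had too little data by the deposited status and 5 to 10 had failed. FPKM are not counts, so no count test was the main test. Low genes whose value and interval imply under 100 fragments came out as whole fragments for 80.2% to 81.0% of genes (tolerance 0.05). The depth was estimated from the implied fragments of all entries of status OK, most of which that check does not cover. It was 28000000, 38300000, 25700000 and 24800000 fragments for mESC 1 to 4 and 38600000, 29700000, 25300000 and 36000000 for mEpiSC 1 to 4. The 10 most abundant genes took 4.7% to 9.1% of all FPKM.

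Samples were grouped by the labels. Differences between states were tested with limma 3.58.1 (trend and robust options, statmod 1.5.0, R 4.3.3) on log2(FPKM + 1) for 11556 genes with at least 1 FPKM in at least 4 libraries, at a Benjamini-Hochberg adjusted p under 0.05; a second count required at least a 2-fold change. Genes were called similar when the 95% interval of the log2 fold change lay within −1 to 1. Lines were compared in a limma fit with 1 mean per line, by the contrast of ESF175/1 minus ESF122 and by an F test over the 3 mEpiSC lines. The 22 gene lists were naive, general and primed pluripotency, primitive streak, neuroectoderm, the Nodal, LIF, FGF and Wnt pathways, DNA methylation, germline, adhesion, glycolysis, cytochrome c oxidase, 2-cell-like state, imprinted genes, Hox genes, enhancer-binding cofactors, markers of fibroblasts, primitive endoderm and trophoblast, and sex-chromosome genes. The 21 lists with at least 3 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, and with an estimated correlation. The fits, the lists, the rule for named genes and the first set of other settings were fixed before the data were examined.

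Named genes were the 10 with the largest change in each direction (adjusted p under 0.05, mean of at least 5 FPKM, no overlap between states, status OK in every library, and no symbol of a predicted gene or small RNA); up to 4 members per list with the largest change past the test; all members of the lists for other cell types; the sex-chromosome genes; 13 genes named in advance; the 5 genes of lowest p per line comparison; and 4 genes of highest expression among those at a similar level. These made 134 genes, of which 124 were tested; some of their values are not reported here. Any other gene is said to have been chosen after its values were seen.

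The replicate numbers are shared by the states but name different lines. The correlation across genes of the deviations of same-numbered libraries from their group means was 0.22, 0.15, 0.18 and 0.51 for replicates 1 to 4, all above 0.1, so the numbers were taken to pair the libraries; the pairing comes from the data and not from a label. By this measure mESC 2 correlated best with mEpiSC 3, and mESC 3 with mEpiSC 2. The highest correlation with a library of another number was 0.12, 0.19, 0.21 and −0.24 for replicates 1 to 4. A bound of 0.1 thus does not by itself identify pairs, and only replicate 4 stood clearly apart. Fits with the replicate number as a block were made beside the main ones.

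Every result was computed again with pseudocounts of 0.1 and 5, no filter, a mean of at least 5 FPKM, median ratio scaling, quantile normalization, status OK in all libraries (11518 genes), no trend, the replicate block, the cell line as a random block (correlation 0.47), 1 mean per line and without each library in turn. Chosen after seeing the data were replicates 1 to 3 only, the replicate 4 libraries as a batch term, voom on implied fragments (11518 genes), the mean of the fibroblast markers as a covariate, and leaving out chromosome 14.

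Sequence shared between genes was checked with a reference of another build (GRCm38, GENCODE vM21), used only for names, transcript lengths, GC content and the share of 50-base windows that also occur in transcripts of other genes; no coordinates were taken from it. The median share was 0.053% in 389 randomly drawn genes, and levels of named genes over 30% are uncertain. No protein-coding transcript matched BC064078, H19, Rps4y2, Tsix, Xist or Zscan4a, so their shared sequence was not checked. The main test was tested on simulated data of 11435 genes, 4 against 4 libraries, at a dispersion of 0.05: of genes changed 1.5-fold, 2-fold and 4-fold, 18%, 80% and 100% were recovered, and 6.1% of calls were false. The simulated libraries were independent, with no effect of line, batch or feeders. These rates therefore do not give the error of the main test on the real libraries, some of which share a line. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for the remaining steps.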

Results

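Gene expression was measured by RNA-seq of polyadenylated RNA in mouse cells of 2 pluripotent states, with 4 libraries of each. Embryonic stem cells (mESC), which represent the naive state of the early inner cell mass, were grown with the cytokine LIF. Epiblast stem cells (mEpiSC), which represent the primed state of the post-implantation epiblast, were grown with the growth factor FGF2. Both were kept on irradiated mouse embryonic fibroblasts, from which they were separated before RNA was extracted. The mESC libraries came from the lines ESF122 (replicates 1 and 2) and ESF175/1 (replicates 3 and 4). The mEpiSC libraries came from EpiSC5 (replicate 1), EpiSC7 (replicates 2 and 3) and EpiSC9 (replicate 4). Values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) as deposited, given as mean ± SD with n = 4 per state unless stated otherwise, and positions are the mm9 intervals listed beside the genes. Fold changes are mEpiSC minus mESC on the scale of log2(FPKM + 1), which understates the change of low genes. Each library listed 23699 entries, of which 10947 to 11524 were at 1 FPKM or more, and its intervals implied 24800000 to 38600000 fragments. No label says that libraries of 1 line came from separate cultures, so p-values measure only the spread between libraries, which may be technical.

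The libraries fell into the labelled states. Across the 11556 genes tested, the Pearson correlation of log2 values was 0.931 to 0.971 between mESC libraries, 0.897 to 0.982 between mEpiSC libraries and 0.781 to 0.891 between states; these are correlations across genes, which are not independent replicates. The first principal component held 63.2% of the variance and parted the states. The second held 16.9% and set both replicate 4 libraries apart, with scores of 33.5 in mESC 4 and 48.9 in mEpiSC 4 against −20.6 to −8.8 in the other 6 libraries.

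**Figure D1:**
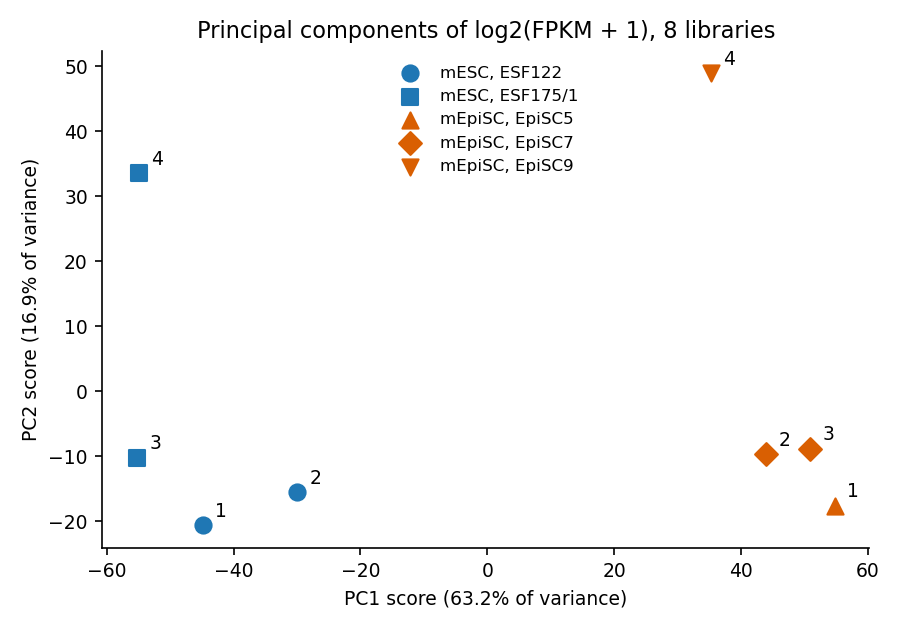
Principal component scores of the 8 libraries from log2(FPKM + 1) of 11556 genes, with PC1 (63.2% of variance) on the x axis and PC2 (16.9%) on the y axis; each point is 1 library, coloured by state and shaped by cell line. The states part along PC1, and replicate 4 of each state lies above the other libraries along PC2.

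The first comparison asked which genes differ between the naive and the primed state, the 2 states whose enhancers the series concerns. Of 18 naive pluripotency factors 17 were lower in mEpiSC than in mESC, and several were nearly absent there. Zfp42, the marker also called Rex1 (chromosome 8, 44380421 to 44392363), measured 130.1 ± 45.4 FPKM in mESC and 0.193 ± 0.207 in mEpiSC, a log2 fold change of −6.73 (SE 0.25; limma, Benjamini-Hochberg adjusted p = 1.0e-06). Esrrb, an orphan nuclear receptor of the naive network, measured 58.7 ± 18.9 against 0.927 ± 0.617 FPKM (log2 −4.94, SE 0.28). Tdh, the threonine dehydrogenase of mESC metabolism, measured 59.6 ± 13.9 against 0.156 ± 0.154 FPKM (log2 −5.70, SE 0.18). In the other direction Cyp26a1, which degrades retinoic acid, rose from 0.649 ± 0.636 to 76.1 ± 72.6 FPKM (log2 5.22, SE 0.52; adjusted p = 2.1e-04).

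In all, 4305 genes (37.3% of those tested) passed the limma test at a Benjamini-Hochberg adjusted p under 0.05, of which 2665 were higher and 1640 lower in mEpiSC. At least 2-fold differences were found for 1748 of them, 1148 higher and 600 lower. The counts were 2842 and 1586 with the cell line as a random block, and 1422 and 1124 with 1 mean per line, so the number of calls rests in part on treating libraries of 1 line as separate samples. The share of calls that were higher in mEpiSC was 61.9% as deposited, 51% after median ratio scaling and 49.8% after quantile normalization; the median log2 fold change of all genes was 0.083, −0.014 and −0.019 in the same order. Values of the 4 mESC and 4 mEpiSC libraries did not overlap for 4285 genes (37.1%, against 2.86% by chance if all libraries were independent). Some libraries share a line, which would raise the share by chance, so that baseline is too low. Of 1817 genes called at 2-fold or more from replicates 1 to 3 alone, a check chosen after the data were seen, 1739 (95.7%) had the same direction between the replicate 4 libraries.

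By the rule for the largest changes, the genes that fell most also included Dppa5a (453 ± 107 to 1.08 ± 1.32 FPKM, log2 −7.92, SE 0.36), Dppa4 (41.1 ± 6.60 to 0.158 ± 0.104 FPKM, log2 −5.17, SE 0.15; chromosome 16, 48283848 to 48294405), Fmr1nb (log2 −5.37, SE 0.20) and Triml2 (log2 −5.39, SE 0.25). Dnmt3l, a cofactor of de novo DNA methylation, fell from 113 ± 38.8 to 0.824 ± 0.936 FPKM. A further 3 were entries named for ribosomal proteins: Rps4y2 (438 ± 216 against 0.943 ± 0.610 FPKM), Rpl29 (143.3 ± 44.6 against 0.145 ± 0.057 FPKM) and Rpl10l (79.8 ± 38.6 against 0.0484 ± 0.0208 FPKM). Of 50-base windows of their transcripts, 47.9% for Rpl29, 38.6% for Dppa5a and 35.9% for Dppa4 also occur in other genes, so these levels are uncertain; the share was 7.60% for Rpl10l. The level of Rps4y2 is uncertain too, since no protein-coding transcript matched its symbol and its shared sequence was not checked.

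The genes that rose most included Cer1, a secreted antagonist of Nodal and BMP (chromosome 4, 82527655 to 82531055), at 1.89 ± 2.94 FPKM in mESC and 270.5 ± 380.7 in mEpiSC (log2 5.98, SE 0.93; adjusted p = 0.0016). Its level in EpiSC5, 838.94 FPKM, stood apart from the 33.83 to 121.82 of the other mEpiSC libraries. Slc39a8, a zinc transporter, rose from 1.23 ± 1.04 to 39.5 ± 13.5 FPKM (log2 4.23, SE 0.32; adjusted p = 4.3e-05). Asb4 (log2 4.40, SE 0.37), Gdpd3 (3.96, SE 0.38), BC064078 (3.75, SE 0.20) and Chst1 (3.69, SE 0.35) rose as well. Amot (log2 4.55, SE 0.91), Fgf5 (3.89, SE 0.73) and Spink3 (3.79, SE 0.86) completed the 10, and with 1 mean per line their adjusted p was 0.081, 0.050 and 0.077.

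**Figure D2:**
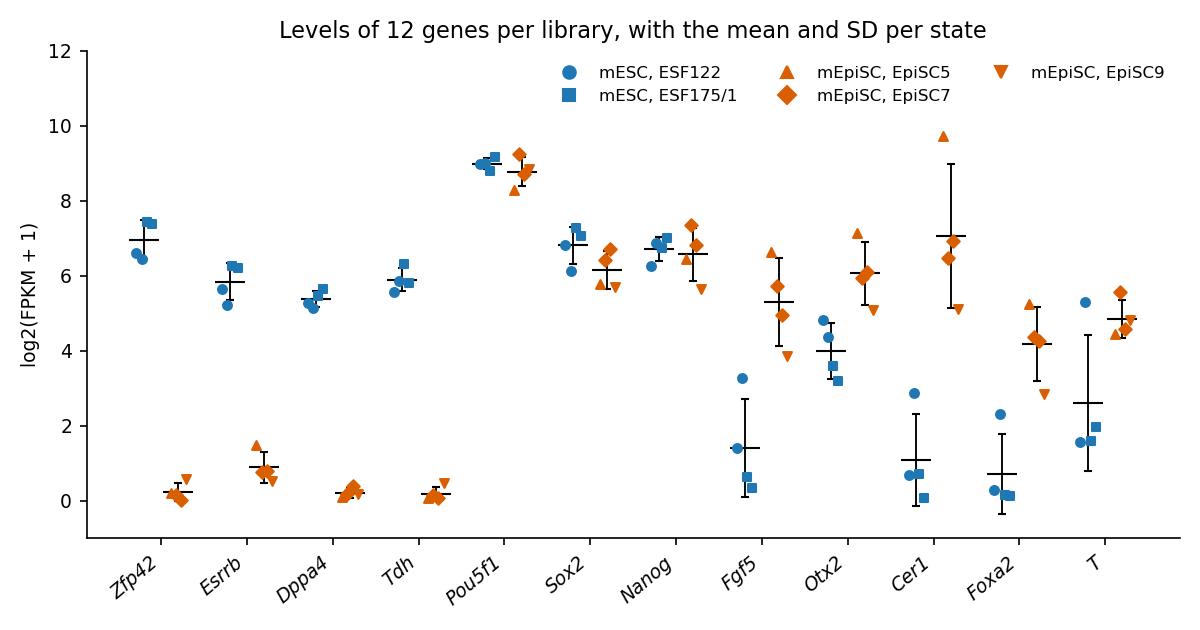
Levels of 12 genes on a log2(FPKM + 1) axis, with a point for each of 4 mESC (blue) and 4 mEpiSC (orange) libraries shaped by cell line, and the mean with SD per state. Zfp42, Esrrb, Dppa4 and Tdh part the states widely, Pou5f1, Sox2 and Nanog overlap, and T in mESC 2 (38.8 FPKM) lies among the mEpiSC values.

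Of the 22 gene lists fixed before the data were examined, the naive list moved most. Of its 18 members 17 fell and none rose (18 fell adjusted over the list alone), and the list was lower as a set (limma camera, adjusted p = 1.8e-40). The remaining member, Nr5a2, a nuclear receptor singled out after its values were seen, was at 14.28 FPKM in EpiSC9 but at 0.06 to 0.33 FPKM in the other mEpiSC libraries (adjusted p = 0.077; 0.033 with the replicate number as a block).

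The core pluripotency factors behaved differently. Pou5f1, also called Oct4, measured 507.8 ± 50.6 FPKM in mESC and 449.6 ± 121.3 in mEpiSC (log2 −0.21, SE 0.20; adjusted p = 0.44). Nanog measured 107 ± 22.0 and 102.5 ± 47.2 FPKM (adjusted p = 0.74). Sox2 measured 116 ± 36.1 and 73.5 ± 25.8 FPKM (log2 −0.66, adjusted p = 0.11), a difference that passed the test without mESC 2 (log2 −0.89, adjusted p = 0.036). In the general pluripotency list 3 of 12 members fell and none rose, also adjusted over the list alone: Dppa4, Utf1 (177 ± 54.4 to 54.6 ± 44.0 FPKM) and L1td1. The call of L1td1 was lost without mESC 1, mESC 3 or mEpiSC 3 (adjusted p = 0.055, 0.062 and 0.062), and that of Utf1 with 1 mean per line (0.12). The list was lower as a set (adjusted p = 4.4e-04). It counted 6 lower members with the replicate block, and 2 higher and 4 lower without mEpiSC 4.

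Primed epiblast genes went both ways, with 8 of 16 higher and 2 lower, also adjusted over the list alone, and no shift of the list as a whole past the test (adjusted p = 0.39). With the replicate block 4 were lower. With the mean of the fibroblast markers as a covariate, a fit chosen after the data were seen, 1 was higher and 2 lower and the list's direction turned negative (adjusted p = 0.92). That mean moved with the state, at 0.86 to 3.64 on the log2 scale in mESC and 3.05 to 4.83 in mEpiSC. Fgf5 rose from 2.76 ± 3.94 to 48.5 ± 36.8 FPKM, Otx2, a homeobox factor of the epiblast and forebrain, from 16.6 ± 8.72 to 75.4 ± 45.8 FPKM, and Cdh2 (N-cadherin) from 1.41 ± 0.880 to 21.8 ± 8.55 FPKM. With 1 mean per line the adjusted p of Otx2 was 0.095; with the fibroblast covariate Otx2 was at log2 0.81 (adjusted p = 0.12) and Fgf5 at log2 2.69 (adjusted p = 0.070). Grhl2, an epithelial transcription factor, fell (log2 −1.89, SE 0.30). Lin28b, a repressor of let-7 maturation, rose modestly (log2 0.76, SE 0.18; 0.10 with 1 mean per line). Dnmt3b, a de novo DNA methyltransferase, measured 146 ± 53.4 and 103.5 ± 42.4 FPKM (adjusted p = 0.33; 0.022 with the replicate block).

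Primitive streak and mesendoderm genes were higher in mEpiSC as a set (adjusted p = 0.0060; adjusted p = 0.43 with an estimated correlation), with 8 of 11 tested members higher and none lower (10 adjusted over the list alone). With the fibroblast covariate the call was lost (adjusted p = 0.14) and 2 members were higher. Besides Cer1, Foxa2, a factor of endoderm and node, rose from 1.09 ± 1.90 to 20.3 ± 12.7 FPKM (log2 3.46, SE 0.60), and Gsc and Lhx1, homeobox factors of the organizer, rose by log2 3.22 and 3.49 (adjusted p = 0.068 and 0.13 with 1 mean per line). T (brachyury) measured 11.4 ± 18.3 and 29.5 ± 11.8 FPKM, with 38.8 FPKM in mESC 2 against 1.95 to 2.94 FPKM in the other mESC libraries. Its call (adjusted p = 0.047) was lost on leaving out any 1 library except mESC 2, with adjusted p from 0.069 without mEpiSC 4 to 0.12 without mESC 3. For all 11 tested members the highest mESC value was that of mESC 2.

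Signalling lists moved in part. In the Nodal/Activin list 7 of 15 members rose and none fell (8 and 2 adjusted over the list alone; list adjusted p = 0.12), among them Cer1 and Cfc1, the Nodal coreceptor Cryptic (0.373 ± 0.586 to 15.5 ± 13.6 FPKM); without mESC 3 and without mEpiSC 2 the higher members were 4, while 1 was lower without mEpiSC 2, and the list had 2 lower members with the replicate block and without mEpiSC 4, where it reached an adjusted p of 0.0496. In the FGF/ERK list 6 of 14 rose and 4 fell, also adjusted over the list alone (list adjusted p = 0.82), with 2 higher without mESC 3 and 3 without mEpiSC 3. Fgf4 fell from 52.0 ± 15.7 to 2.97 ± 1.17 FPKM while Fgf8 rose from 7.04 ± 9.73 to 40.3 ± 20.5 FPKM (adjusted p = 0.064 with the cell line as a random block). The list's median (0.60) and mean (0.26) were positive although its test statistic was negative. In the LIF/STAT3 list 2 of 12 rose and 4 fell, also adjusted over the list alone (list adjusted p = 0.12; 0.036 without mESC 2). Klf4 fell from 16.4 ± 7.12 to 2.66 ± 0.258 FPKM, Tfcp2l1 from 10.99 ± 2.77 to 1.02 ± 0.321 FPKM, and Junb rose from 17.1 ± 2.61 to 47.9 ± 13.5 FPKM. In the Wnt list 6 of 16 rose and 1 fell, also adjusted over the list alone (list adjusted p = 0.35): the secreted antagonist Dkk1 rose by log2 3.09 (SE 0.42), and Notum, which inactivates Wnt proteins, fell (log2 −1.85, SE 0.26), with 31.7% of its windows shared with other genes.

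Genes of DNA methylation and of the germline were lower in mEpiSC. Of 10 DNA methylation members 6 fell and none rose (6 and 1 adjusted over the list alone; list adjusted p = 9.8e-05; 1 higher without mEpiSC 4 and with the replicate block). Besides Dnmt3l these included Tet1 (51.8 ± 15.6 to 16.2 ± 6.55 FPKM) and Tet2 (11.2 ± 3.22 to 3.08 ± 0.668 FPKM), which oxidize methylcytosine, and Zfp57 (57.0 ± 17.1 to 17.7 ± 3.56 FPKM), which guards imprints. Of 14 germline members 11 fell and 1 rose, also adjusted over the list alone (list adjusted p = 8.9e-14). Mael, of the piRNA pathway, fell from 19.1 ± 7.52 to 0.0468 ± 0.0197 FPKM and Dazl, a germ cell RNA-binding protein, from 12.9 ± 8.73 to 0.0122 ± 0.0107 FPKM. Sycp3, of the synaptonemal complex, fell by 3.79 on the log2 scale and Tuba3a by 4.63, with 50.4% and 35.3% of their windows shared with other genes. The 3 tested 2-cell-like genes, Zscan4a, Zscan4c and Zscan4d, all fell, also adjusted over the list alone, from 2.97 to 4.84 FPKM to near 0 (list adjusted p = 0.021; adjusted p = 0.39 with an estimated correlation; 0.056 without mEpiSC 4), and reads of these near-identical copies cannot be assigned with certainty.

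Imprinted genes were higher in mEpiSC, with 11 of 18 higher and 2 lower (12 and 2 adjusted over the list alone; list adjusted p = 0.0012; adjusted p = 0.18 with an estimated correlation). Grb10, an adaptor of growth factor receptors, rose from 45.4 ± 5.18 to 307 ± 122 FPKM (log2 2.66, SE 0.24), and Nnat, a membrane proteolipid, from 8.26 ± 2.19 to 109 ± 36.6 FPKM. The noncoding RNA H19 rose from 18.7 ± 21.5 to 157 ± 40.2 FPKM, with 50.47 FPKM in mESC 1, and Igf2 rose by log2 2.81 (SE 0.65) with 75.9% of its windows shared with other genes. None was lower without mESC 1 or mESC 3, and 1 was without mESC 2, mEpiSC 1, mEpiSC 3 or mEpiSC 4. Fibroblast markers had a mean log2 level of 3.64 in mESC 1 and of 0.86 to 1.97 in the other mESC libraries, and with that mean as a covariate the list had 7 higher and 1 lower member (adjusted p = 0.050). In that fit Igf2 had a log2 fold change of 1 and lost its call (limma, adjusted p = 0.13).

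Cell adhesion genes went both ways, with 8 of 19 higher and 3 lower (9 and 3 adjusted over the list alone; list adjusted p = 0.20; 5 lower without mESC 4, and with the replicate block). The keratins Krt8 and Krt18 rose from 2.98 ± 2.51 to 32.5 ± 24.6 and from 4.43 ± 2.55 to 54.1 ± 44.7 FPKM, whereas Cldn4, a tight junction claudin, fell from 24.3 ± 5.79 to 4.94 ± 6.19 FPKM (0.11 with 1 mean per line), with 14.16 FPKM in mEpiSC 4. In the neuroectoderm list 3 of 6 tested members rose and 1 fell, also adjusted over the list alone (list adjusted p = 0.39; 1 rose without mESC 3): Pax3 rose from 0.0571 ± 0.0414 to 1.33 ± 0.321 FPKM and Tubb3, a neuronal tubulin, fell from 25.2 ± 8.16 to 8.47 ± 4.18 FPKM (0.085 with 1 mean per line).

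Of the metabolic lists, 5 of 15 cytochrome c oxidase members fell and 1 rose, also adjusted over the list alone (list adjusted p = 0.082; 0.017 with the replicate block, which gave 7 lower and 2 higher). Cox5a fell from 288 ± 39.7 to 168 ± 27.4 FPKM and Cox6c from 146 ± 11.8 to 90.3 ± 10.2 FPKM; with 1 mean per line their adjusted p was 0.077 and 0.066, and 32.0% of the windows of Cox5a are shared. Without mEpiSC 4 the list had 10 lower members and an adjusted p of 0.0083; the lower members were 3 without mESC 3 or mEpiSC 3, and the higher member was lost without mESC 3 or mEpiSC 2. In the glycolysis list 2 of 17 fell and none rose, also adjusted over the list alone (list adjusted p = 0.71): Pfkp, a phosphofructokinase, fell from 40.1 ± 15.9 to 9.37 ± 6.39 FPKM (0.084 with 1 mean per line) and Pdk1 from 53.6 ± 6.89 to 24.5 ± 11.3 FPKM (0.051 without mESC 1). The counts were 1 lower without mESC 1, 1 higher and 3 lower without mESC 4 or mEpiSC 2, 2 higher and 2 lower without mEpiSC 1, and 2 higher and 3 lower with the replicate block; the list's median was 0.07 and its mean −0.04. Gapdh, a usual reference gene, was listed at 0.85 to 1.66 FPKM in every library, with 82.5% of its windows shared with other genes.

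**Figure D3:**
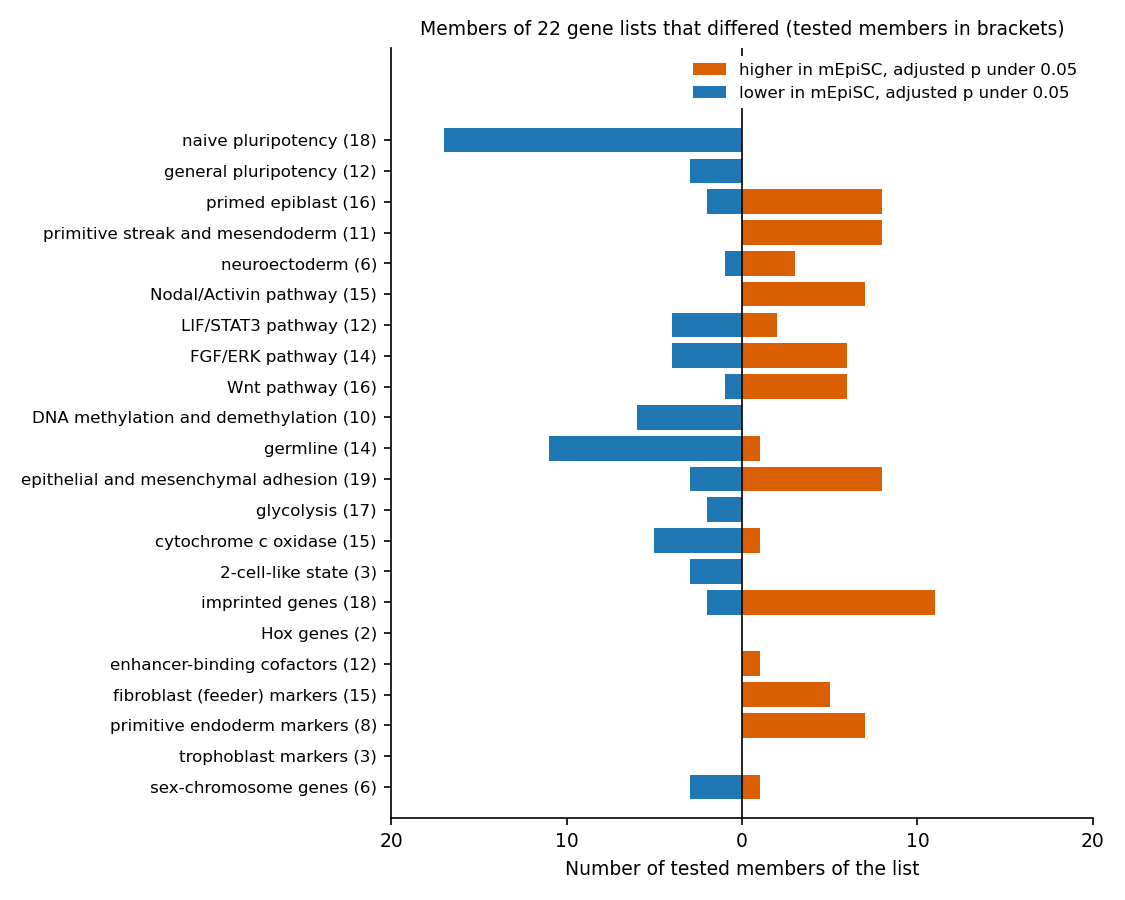
Bars give the number of tested members of each of 22 gene lists that were higher (orange, to the right) or lower (blue, to the left) in mEpiSC at a limma adjusted p under 0.05, with the number tested in brackets. The naive list has 17 of 18 members lower, and the imprinted list 11 of 18 higher.

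Markers of other cell types were measured alongside. Of 15 tested fibroblast markers 5 rose and none fell, also adjusted over the list alone (list adjusted p = 0.021; adjusted p = 0.61 with an estimated correlation). These were Acta2 (1.49 ± 0.722 to 23.3 ± 11.9 FPKM), Mmp2 (8.45 ± 4.37 to 27.7 ± 7.51 FPKM), Pdgfrb, Tagln (48.3% of windows shared) and Thy1; the call of Thy1 was lost without mESC 3, mESC 4, mEpiSC 1 or mEpiSC 3 (adjusted p = 0.078, 0.060, 0.068 and 0.076). Col1a1, a collagen of fibroblasts, was at 78.36, 9.71, 13.93 and 0.48 FPKM in mESC 1 to 4 and at 159.04, 84.49, 51.45 and 7.92 FPKM in mEpiSC 1 to 4 (adjusted p = 0.20; 0.0048 with the replicate block). With the replicate block 15 of the markers were higher, and without mESC 1, 12 were; the list's adjusted p was 0.070 without mESC 2, 0.097 without mESC 4 and 0.084 without mEpiSC 1. Of 8 primitive endoderm markers 7 rose and none fell, also adjusted over the list alone (list adjusted p = 0.021; adjusted p = 0.39 with an estimated correlation; 0.089 without mESC 2 and 0.056 without mESC 4). With the fibroblast covariate 0 of these 8 passed in limma, 5 had an unadjusted p under 0.05 and the list's adjusted p was 0.21. Sparc rose from 40.6 ± 18.7 to 124 ± 41.5 FPKM, and Sox17 from 0.161 ± 0.175 to 7.72 ± 7.46 FPKM (0.069 with 1 mean per line). Gata6 was at 26.43 FPKM and the untested Gata4 at 18.88 FPKM in EpiSC5, against at most 4.41 and 1.20 FPKM in the other mEpiSC libraries; the call of Gata6 was lost without mESC 1, mESC 3 or mEpiSC 3 (adjusted p = 0.064, 0.063 and 0.052). Of 3 tested trophoblast markers 0 passed in limma, also adjusted over the list alone (list adjusted p = 0.81). At an unadjusted p under 0.05 there were 2, and of these Tead4 (2.78 ± 0.651 and 1.50 ± 0.986 FPKM, adjusted p = 0.076) passed without mEpiSC 1 (0.0097).

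The remaining lists were those of enhancer-binding cofactors, Hox genes and sex-chromosome genes. Of 12 cofactors 1 rose and none fell (0 adjusted over the list alone; list adjusted p = 0.82). That was Kdm6a, an X-linked histone demethylase (13.3 ± 1.04 to 22.9 ± 7.15 FPKM), whose call was lost without mESC 1, mESC 3, mESC 4, mEpiSC 2 or mEpiSC 3 (adjusted p = 0.058, 0.056, 0.060, 0.074 and 0.068). Without mEpiSC 4, and with the replicate block, 3 cofactors were higher, and without both replicate 4 libraries, a fit chosen after the data were seen, 8 were. Both replicate 4 libraries had low values of several: Mll2, a histone methyltransferase singled out after its values were seen, was at 0.55 FPKM in both and at 8.50 to 14.23 FPKM elsewhere. Among Hox genes only 2 were expressed highly enough to test, and in limma 0 passed over all genes, while 2 were higher adjusted over the list alone and at an unadjusted p under 0.05. Over all genes 1 was higher without mESC 2 and with the replicate block, and 2 were without mEpiSC 1. Of 6 sex-chromosome genes 1 rose and 3 fell (1 and 4 adjusted over the list alone; list adjusted p = 0.12). Without mEpiSC 1 the list's adjusted p was 2.4e-08 and 5 were lower, and without mEpiSC 2 or mEpiSC 3, 1 was lower. Xist, the RNA of the inactive X chromosome, was at 36.08 to 41.02 FPKM in EpiSC7 and EpiSC9, at 1.75 FPKM in EpiSC5 and at most 1.66 FPKM in mESC (log2 3.55, SE 0.83; adjusted p = 0.0096, and 0.14 with 1 mean per line). The Y-linked Ddx3y was at 12.72 to 30.36 FPKM in mESC and EpiSC5 and at most 0.41 FPKM in EpiSC7 and EpiSC9 (adjusted p = 0.054; 3.0e-05 without mEpiSC 1; 0.030 with the replicate block). Y-linked RNA with little Xist thus marked every mESC library and EpiSC5, and Xist with little Y-linked RNA marked EpiSC7 and EpiSC9. Calls between the states of these genes and of the X-linked Kdm6a therefore cannot be told apart from a difference in sex between the lines. Kdm6a was at 27.66 and 30.39 FPKM in EpiSC7, 16.26 in EpiSC5 and 17.37 in EpiSC9. Of the 9 lists past the test of the whole set, the naive, general pluripotency, DNA methylation and germline lists also passed with an estimated correlation (adjusted p = 1.7e-09, 0.016, 0.0083 and 0.0038); 9 lists passed in both line fits.

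Other fits moved several of these counts of members past the test. With 1 mean per line there were 1 higher and 1 lower in the primed and Wnt lists, and 1 higher and 2 lower in the FGF and LIF lists. In that fit 4 were higher and none lower in the streak and Nodal lists, 6 in the adhesion list, 7 in the imprinted list, and 1 in the neuroectoderm and primitive endoderm lists, while 1 was lower and none higher in the general pluripotency and sex-chromosome lists. There limma called 0 in the glycolysis, cytochrome c oxidase and cofactor lists, where 3, 5 and 0 members had an unadjusted p under 0.05. With the cell line as a random block there were 7 higher and 1 lower in the primed list, 1 and 1 in the neuroectoderm list, 1 and 3 in the LIF and FGF lists, only higher ones in the Nodal (4) and imprinted (8) lists, only lower ones in the cytochrome c oxidase list (3), and in limma 0 cofactors (1 at an unadjusted p under 0.05).

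With the fibroblast covariate there were 3 higher in the Nodal list, 2 higher and 2 lower in the FGF list, 1 higher and 2 lower in the LIF list, 1 higher and 1 lower in the Wnt and cytochrome c oxidase lists, 1 higher in the neuroectoderm and Hox lists and 2 higher in the glycolysis list. The sex-chromosome list had 1 higher and 4 lower (adjusted p = 0.030), and the fibroblast list, from which the covariate was made, 2 and 2 (adjusted p = 0.29). In limma 0 passed in the 2-cell (adjusted p = 0.10) and cofactor lists, where 3 and 2 members had an unadjusted p under 0.05. From replicates 1 to 3 alone there were 2 higher and 4 lower in the general pluripotency list, 1 and 6 in the DNA methylation list, 8 and 6 in the adhesion list, 2 and 2 in the glycolysis list and 10 lower in the cytochrome c oxidase list (adjusted p = 0.0068); the calls of the 2-cell and fibroblast lists were lost (adjusted p = 0.13 and 0.075). With the replicate 4 libraries as a batch term, also chosen after the data were seen, there were 6 lower in the general pluripotency list, 8 higher and 4 lower in the primed list, 8 and 2 in the Nodal list, 1 and 7 in the DNA methylation and cytochrome c oxidase lists (the latter at an adjusted p of 0.025), 9 and 5 in the adhesion list, 2 and 3 in the glycolysis list, 6 and 1 among cofactors, and 1 Hox gene and 10 fibroblast markers higher; the call of the 2-cell list was lost (adjusted p = 0.070).

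Scaling, the pseudocount and filters moved some of them too. After median ratio scaling there were 5 lower in the general pluripotency list and 5 higher and 2 lower in the Nodal list. After quantile normalization there were 7 and 2 in the Nodal list, 2 and 3 in the glycolysis list, 9 and 1 in the imprinted list, 7 lower and none higher in the cytochrome c oxidase list and 1 lower trophoblast marker. In both, limma called 0 cofactors, with 1 at an unadjusted p under 0.05. With a pseudocount of 5 the calls of the 2-cell and primitive endoderm lists were lost (adjusted p = 0.097 and 0.051). With a mean of at least 5 FPKM, which leaves fewer genes to test and none of the 2-cell list, the primitive endoderm list had 3 higher (adjusted p = 0.067), the fibroblast and Wnt lists 3, the adhesion list 5, and the germline list 5 lower; 1 was lower in the primed, imprinted and sex-chromosome lists. Without a filter 1 imprinted gene was lower. With voom, chosen after the data were seen, there were 7 higher and 1 lower in the primed list, 3 lower in the cytochrome c oxidase list, 1 lower trophoblast marker, and 1 higher and 4 lower in the sex-chromosome list (adjusted p = 0.022). Without chromosome 14 there were 5 higher in the primed list, but that fit drops its members Otx2, Sall2, Zic2 and Zic5, so fewer were tested.

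The next comparison asked which genes were used at a similar level in both states. For 7187 genes (62.2% of those tested) the 95% confidence interval of the log2 fold change lay within −1 to 1, against 6345 with the cell line as a random block and 5607 with 1 mean per line. Among the highest in expression outside the lists were Eef1a1, a translation elongation factor (1922 ± 465 and 1953 ± 472 FPKM in mESC and mEpiSC; log2 0.02, SE 0.22), and Hsp90ab1, a chaperone (1674 ± 127 and 1561 ± 106 FPKM; log2 −0.10, SE 0.12). The ribosomal protein gene Rpl8 (1708 ± 401 and 1440 ± 436 FPKM) was highest in replicate 4 of each state; its adjusted p was 0.41, and 0.038 with the replicate block. Actb, a cytoskeletal actin, measured 1411 ± 95.7 and 1264 ± 161 FPKM, and 60.6% of the windows of Eef1a1 are shared with other genes. Of the 7187 genes, 1248 also passed the test of a difference, with a change bounded below 2-fold on the scale of log2(FPKM + 1). In FPKM the change of low genes can be larger. Among the genes tested, 1312 were neither called nor bounded. With pseudocounts of 0.1 and 5 the genes at a similar level were 6118 and 9572.

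Differences between the 2 mESC lines concerned few genes by the test. Ipp, an actin-binding Kelch protein (chromosome 4, 116180154 to 116210840), was at 163.03 and 138.06 FPKM in the ESF122 libraries and at 5.52 and 7.01 FPKM in those of ESF175/1 (log2 −4.39 for ESF175/1 minus ESF122, SE 0.17; adjusted p = 2.3e-04). Baiap2l1, which links membranes to actin, was lower in ESF175/1 too (80.56 and 53.78 against 1.68 and 1.37 FPKM). Entries of 3 ribosomal protein genes were higher in ESF175/1: Rps2 (2.01 and 1.61 against 240.88 and 226.62 FPKM), Rps18 (1.24 and 0.98 against 78.91 and 160.54 FPKM) and Rps26 (44.94 and 49.24 against 444.78 and 571.18 FPKM). Of their windows 71.3%, 86.7% and 38.3% occur in other genes, so these levels are uncertain.

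In this comparison 88 genes passed (limma, 1 mean per line, 2 libraries for each line), 40 higher in ESF175/1 and 48 higher in ESF122, of which 33 also differed between the states; 1723 had an unadjusted p under 0.05. The spread was pooled over 3 lines with 2 libraries each. The count was 23, 16, 18 and 18 without mESC 1, mESC 2, mEpiSC 2 and mEpiSC 3, and 1497 without mESC 3, so it rests on single libraries.

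Differences among the 3 mEpiSC lines included single genes and 1 chromosome. Pga5, a pepsinogen (chromosome 19, 10743447 to 10752561), was at 203.42 FPKM in EpiSC5 and at 2.85 to 4.26 FPKM in the other mEpiSC libraries. Rps3a was at 91.72 FPKM in EpiSC9 and at 2.64 to 3.62 FPKM in the other mEpiSC libraries, with 71.0% of its windows shared. Ngdn (chromosome 14, 55634291 to 55642974) was at 202.02 and 188.91 FPKM in the EpiSC7 libraries, 25.12 in EpiSC5 and 37.64 in EpiSC9. Haus4, of the augmin complex of the spindle (chromosome 14, 55160622 to 55173198), was at 94.42 and 93.73 FPKM in EpiSC7, 10.11 in EpiSC5 and 22.00 in EpiSC9. The fifth gene of the rule, Ddx3y, followed the Y-linked pattern given above. In the limma F test the adjusted p of these 5 was 0.0014 to 0.0033.

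These last genes lay in a block. For 19 genes from Oxa1l to Ngdn (chromosome 14, 54980525 to 55642974), chosen after their values were seen, the median log2 difference of EpiSC7 from the mean of EpiSC5 and EpiSC9 was 1.82 (3.53-fold; quartiles 1.39 and 2.25). For 135 genes from there to the end of the chromosome (56097595 to 123312387) the median was −0.85 (0.55-fold; quartiles −1.01 and −0.64), and for the 125 genes before the block it was 0.13. Both EpiSC7 libraries were above EpiSC5 and EpiSC9 for 94.7% of the block and below both for 83.7% of the distal genes. On other chromosomes these shares were 16.5% and 15.4%, and by chance 16.7% each way. Of the genes before the block 30.4% were above both and 7.2% below both, so that part leaned upward too. The segments were drawn from these same values, so the shares describe them and test nothing; genes counted had a mean of at least 5 FPKM.

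Among the lines 300 genes passed (limma F test, 2857 with an unadjusted p under 0.05), 106 of which also differed between the states, and 53 of the 300 (17.7%) were on chromosome 14, which holds 3.4% of the genes tested. Without that chromosome 164 genes passed. EpiSC5 and EpiSC9 had 1 library each and were assumed to vary like the lines with 2. The pooled spread also held the difference between mESC 3 and mESC 4, which drops out when either is left out. The 1 library of EpiSC9 was mEpiSC 4, which the second principal component set apart. Calls that rest on EpiSC9 cannot be told apart from an effect of that library. The count was 65, 68, 52, 65 and 73 without mESC 1, mESC 2, mEpiSC 2, mEpiSC 3 and mEpiSC 4, and 2215 and 2205 without mESC 3 and mESC 4.

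**Figure D4:**
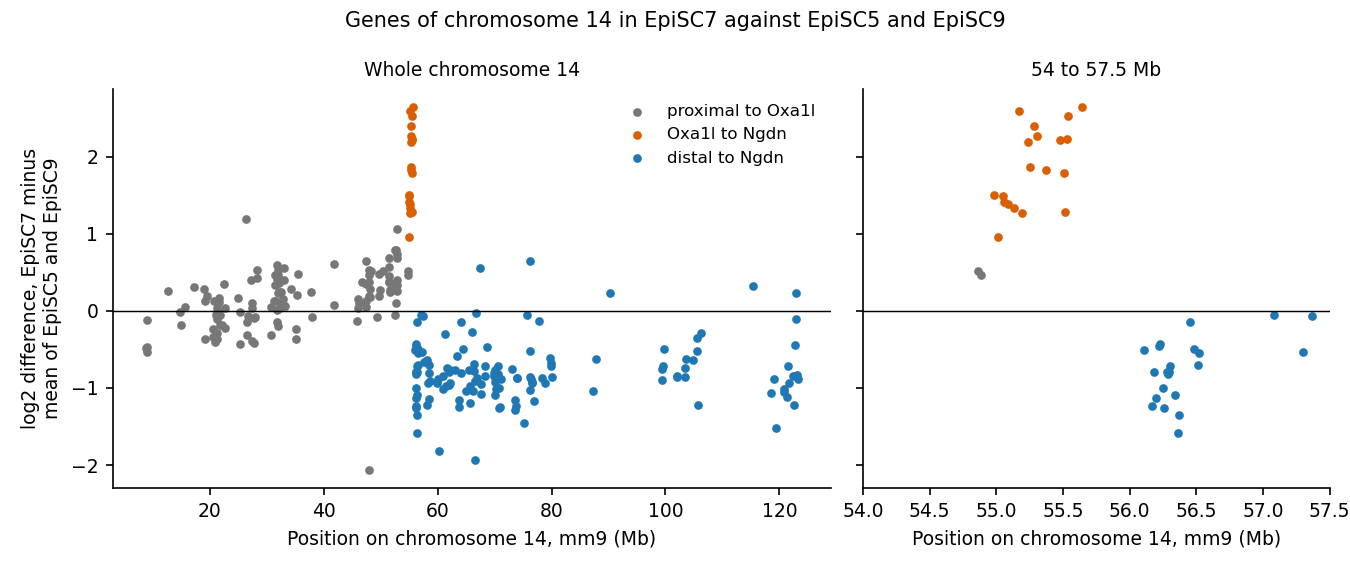
Each point is a gene of chromosome 14 at its mm9 midpoint in Mb (x axis; whole chromosome on the left, the block and its flanks on the right), with the log2 difference of EpiSC7 (2 libraries) from the mean of EpiSC5 and EpiSC9 (1 library each) on the y axis. The 19 genes from Oxa1l to Ngdn have a median of 1.82, and the 135 genes beyond them a median of −0.85.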

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

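The tests of replicate 4 and of the fibroblast markers, and the minimum of 1 FPKM for calling a library outlying, were chosen after the results were seen; the tests on other splits of the libraries were fixed before.

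Replicate 4 of each state stood apart on the second principal component, where mEpiSC 4 had a score of 48.9 against −17.6 to −8.8 in the other mEpiSC libraries, the 1 outlying value of 12 groups of library measures tested. GC content is argued against (rank correlation across genes, which are not independent, of at most 0.06 in size). A bias by transcript length remains a candidate explanation, with rank correlations across genes of −0.37 in mESC 4 and −0.42 in mEpiSC 4 for their deviation from the other libraries of their state, and the long transcript Malat1, chosen after its values were seen, was low (19.49 and 19.26 FPKM against 91.89 to 172.45 elsewhere). A difference between the mESC lines as the whole cause stays open. Between mESC 4 and the mean of mESC 1 and 2, 886 genes differed 2-fold. In mESC 3, of the same line, 24.6% of these differed 2-fold in the same direction, and 87.6% went the same way at any size. Genes chosen by mESC 4 are bound to differ less elsewhere, and both differences share mESC 1 and 2. On the second principal component mESC 3 scored −10.2, away from the 33.5 of mESC 4, but this rests on 1 library. For mEpiSC 4 the line cannot be told apart from the library, because EpiSC9 has 1 library.

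Fibroblast markers varied within each state, Col1a1 by 330.6-fold over the 8 libraries. Over all 14 other markers the ratio to Col1a1 varied by a median of 4.80-fold, and 9 stayed within 10-fold (2.13 to 9.49), as RNA of feeder fibroblasts could give; 1 of the 9, S100a4, shares 56.3% of its windows with other genes. Fibroblast-like cells arising in the cultures would give the same and cannot be told apart from feeders, since the 9 markers would keep the ratio under either explanation; this comparison first asked whether mESC 1 exceeded mEpiSC 4 (it did for all 9), and was changed after that result because 1 library excludes nothing. Whether feeder RNA is the whole cause for the 5 markers past the test (Thy1, Mmp2, Pdgfrb, Acta2 and Tagln) stays open: their ratio varied by a median of 69.0-fold over all libraries, but by 30-fold without mESC 4 and 6.99-fold (2.24 to 40) in replicates 1 to 3, and a marker that passes a test needing little spread within a state is bound to part from Col1a1. The 69.0-fold had first been taken to exclude that explanation, and expression of these 5 by the epiblast stem cells themselves was not tested.

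Of 227 groups of 4 values of a named gene, 45 held a library far from the others. About 11 (1 in 20) would be expected by chance if values were normally spread and genes independent. FPKM are skewed, genes vary together, and some named genes were chosen for differing between lines. The excess therefore tests nothing, and the cases are only described. In mEpiSC 1 (EpiSC5) there were 16. It was high for Amot (538.93 FPKM against 17.28 to 96.01 in the other mEpiSC libraries), Cer1 (838.94 against 33.83 to 121.82), Cyp26a1 (184.14 against 27.74 to 49.35), Gsc (50.25 against 4.72 to 10.06), Lhx1 (93.76 against 2.51 to 10.64), Gata3 (4.84 against 0.17 to 0.60), Gata4 (18.88 against 0.50 to 1.20), Gata6 (26.43 against 1.71 to 4.41), Pga5 (203.42 against 2.85 to 4.26) and Zfp57 (22.99 against 15.52 to 16.66). It was low for Fgf4 (1.23 against 3.42 to 3.70) and Xist (1.75 against 36.08 to 41.02). The Y-linked genes Ddx3y (30.36 against 0.11 to 0.41), Eif2s3y (39.54 against 0.09 to 0.47), Kdm5d (6.32 against 0.02 to 0.06) and Uty (7.09 against 0.03 to 0.08) were high.

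In mESC 2 there were 11, all high: Amot (7.93 FPKM against 1.15 to 2.11 in the other mESC libraries), Asb4 (1.27 against 0.18 to 0.28), Cdh2 (2.72 against 0.88 to 1.06), Cer1 (6.29 against 0.06 to 0.63), Cfc1 (1.25 against 0.03 to 0.13), Fgf5 (8.61 against 0.26 to 1.64), Fgf8 (21.61 against 1.58 to 3.00), Foxa2 (3.95 against 0.09 to 0.23), Lhx1 (1.51 against 0.02 to 0.05), Lin28b (18.02 against 11.91 to 12.60) and T (38.80 against 1.95 to 2.94).

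In mESC 1 there were 5, all markers of fibroblasts or primitive endoderm: Col1a2 (64.11 FPKM against 1.09 to 11.74), Pdgfra (3.04 against 0.45 to 0.88), Postn (7.70 against 0.11 to 1.24), S100a4 (18.66 against 0.43 to 2.47) and Sparc (68.33 against 28.44 to 34.46). In mESC 3 there were 5: Cox7c (27.27 against 21.88 to 22.40), Tfcp2l1 (15.11 against 9.17 to 9.95) and Tsix (2.31 against 1.21 to 1.29) were high, and Acta2 (0.40 against 1.82 to 1.87) and Rpl29 (77.17 against 156.52 to 172.43) were low. In mESC 4 there were 3: Rpl8 (2304.04 against 1468.09 to 1586.53) and Rps4y2 (758.88 against 288.97 to 352.74) were high and Eif2s3y (26.01 against 45.72 to 49.01) was low. In mEpiSC 4 there were 4: Cldn4 (14.16 against 0.88 to 2.44), Dppa5a (3.04 against 0.15 to 0.62) and Rps3a (91.72 against 2.64 to 3.62) were high and Actb (1022.97 against 1338.78 to 1354.50) was low. In mEpiSC 3 there was 1, Sox3 (12.54 against 6.61 to 7.25).

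Of all 35 splits of the 8 libraries into groups of 4, the real one gave the most genes that differ, 4305. The others gave at most 2. The real split also gave the most genes at least 2-fold apart (1748, at most 2 in the others). It gave the fewest at a similar level (7187, at least 7283 in the others). The other splits mix the states, which brings their group means together and puts the state difference into their spread. They are therefore bound to give few calls, and libraries of 1 line were split as if independent. These gene counts thus do not exclude chance. Nor can chance be excluded for the number of lists (9, up to 13 in the others), because 11 of the 35 splits gave as many. The pairing by replicate number comes from the data, and only replicate 4 clearly bears it out. If it holds, the real split is to be compared with the 7 others that part every pair. Those mix the states within each group and gave at most 0 genes, 0 genes of at least 2-fold and 11 lists. They gave at least 7491 genes at a similar level and are too few for a share under 0.05.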

How the results depend on the processing

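Replicates 1 to 3 only, the batch term for replicate 4, voom, the fibroblast covariate and leaving out chromosome 14 were chosen after the results were seen; the other alternatives were planned. The 4305 genes that differ between the states became 2752 with a mean of at least 5 FPKM (fewer genes tested), 2842 with the cell line as a random block, 1422 with 1 mean per line (fewer samples) and 2630 with the fibroblast covariate. The 1748 genes of at least 2-fold became 684 with a pseudocount of 5, which shrinks folds of low genes, 979 with a mean of at least 5 FPKM and 1124 with 1 mean per line. The 9 lists became 5 with the fibroblast covariate and 4 with an estimated correlation. With the covariate the streak, 2-cell, imprinted and primitive endoderm lists lost their call (camera, adjusted p = 0.14, 0.10, 0.050 and 0.21). The fibroblast list, for which the covariate is circular, lost it too. The sex-chromosome list, not among the 9, passed newly. The 7187 genes at a similar level became 14271 with no filter (more genes tested). The 88 genes of the mESC lines became 55 with a mean of at least 5 FPKM. The 300 genes of the mEpiSC lines became 185 and 566 with pseudocounts of 0.1 and 5, 466 with no filter, 159 with a mean of at least 5 FPKM, 186 with median ratio scaling, 176 with replicates 1 to 3 only and 164 without chromosome 14. Where no construction is named, the cause was not tested.

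Leaving out each library gave 3132 to 4789 genes between states, 1532 to 1888 of at least 2-fold, 7 to 10 lists, 6510 to 7196 genes at a similar level, 16 to 1497 for the mESC lines (lowest without mESC 2, highest without mESC 3) and 52 to 2215 for the mEpiSC lines (lowest without mEpiSC 2, highest without mESC 3). With the replicate block there were 5205 genes between states, 1812 of at least 2-fold, 10 lists and 7690 genes at a similar level; other than the cases given in the report it changed no call of a list. Of the fold changes of 124 named genes under the alternatives, 2722 kept their side of the test, 48 passed it newly, 165 no longer passed and 0 reversed. The block, line, batch, voom and covariate fits give no count for the line comparisons. Depth limits genes near 1 FPKM, where changes are understated.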

Other observations

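All tests in this part were chosen after the values were seen, as were the genes named here outside the report.

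Single genes set some libraries apart. Krt19, a simple-epithelial keratin, was at 173.57 FPKM in EpiSC9 and at 4.77 to 11.67 FPKM in the other mEpiSC libraries. Wnt8a, a Wnt ligand of the streak, was at 39.33 FPKM in mESC 2 and at 2.50 to 8.31 FPKM in the other mESC libraries, and Eomes, a T-box factor of the streak, was at 3.30 against 0.90 to 1.41 FPKM. Rn45s, the ribosomal RNA precursor, was at 2394.19 FPKM in mESC 1 and at 205.61 to 399.80 FPKM elsewhere. Deviations of mESC 4 from the mean of the other mESC libraries were centred on their median over all genes. Genes of chromosomes 6 and 8 then had median log2 deviations of 0.28 and 0.22, with 70.3% and 69.4% of them higher. The other chromosomes of mESC 4 lay between −0.11 and 0.08.

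Within the block of chromosome 14 that was high in EpiSC7, Psmb5, a proteasome subunit, was at 302.36 and 273.22 FPKM in EpiSC7, 47.95 in EpiSC5 and 82.01 in EpiSC9, and Efs, a docking protein, at 65.42 and 79.95 against 11.91 and 11.93 FPKM. Beyond it Nedd8, a ubiquitin-like modifier, was at 101.50 and 98.83 FPKM in EpiSC7, 164.78 in EpiSC5 and 196.35 in EpiSC9, and Rb1, the retinoblastoma protein, at 1.79 and 2.62 against 4.28 and 5.90 FPKM.

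A hypothesis is that EpiSC7 carries a copy-number change of chromosome 14, with a loss distal to Ngdn behind the median of −0.85 there (0.55-fold) and a gain from Oxa1l to Ngdn behind that of 1.82. Both stay open, as the segments were drawn from these same values and no DNA was measured here. A technical difference between libraries, which has no reason to follow position, is argued against for both segments: over the other chromosomes the farthest median of a run of as many genes was 0.33 for the 135 distal genes and 0.47 for the 19 of the block, each under 50% of the segment's own median in size. Both of those runs lay on chromosome 12, where 141 genes beyond 80 Mb had a median of 0.32 in EpiSC7, and without that chromosome the runs reached at most 0.12 and 0.29 in size. Runs of 21 genes, used first for both segments, had left the distal one open, as their farthest median was 0.47.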
